A study of Mus musculus with 12 samples.

How the data were processed

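Bulk RNA-seq of mouse small intestinal organoids was analysed from 12 libraries in 4 groups of 3. The organoids, epithelial cultures grown in a basement membrane extract, came from a female mouse of a line with a GFP and diphtheria toxin receptor cassette at Lgr5. Per the labels, the treated cultures received 3 µM CHIR99021, a GSK3 inhibitor that activates Wnt signalling, and 1.5 mM valproic acid, a histone deacetylase inhibitor, for 3 days. They then spent 1 day in ENR medium, which holds EGF, Noggin and R-spondin, and 6 days with 100 ng/mL RANKL, the cytokine that drives M cell differentiation. The RANKL+CSRM617 group also received 40 µM CSRM617, a small molecule described as an inhibitor of the transcription factor ONECUT2. The RANKL II group is the RANKL set that shares a table with the CSRM617 libraries. Control organoids grew in ENR medium for 6 days per the labels. Their sample names begin with CVENR, in which CV may stand for CHIR99021 and valproic acid, but no label spells the prefix out.

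Libraries were made, per the labels, from 1 µg of total RNA after ribosomal RNA depletion and were read as 42-bp pairs. The authors deposited 2 tables of raw gene counts per symbol, 1 for each comparison, which per the submitters' processing notes came from STAR on mm10 (GRCm38) and HTSeq 0.13.5, with DESeq2 1.34.0 also named. The STAR version, the annotation and the strand setting of the counting are not given in the sources used here, so reads of genes that overlap on opposite strands may not have been separated. The authors also deposited 2 normalized tables, whose values were found to be on a log2 scale. Their 17442 and 18531 genes are exactly those whose raw counts sum to at least 10. For genes with over 1000 counts in each library the values differed from log2 raw counts by a constant per library, with an SD of at most 0.025. The exact transformation is not given in the sources used here. A pseudocount of 1 had been planned for these tables and was dropped because the values were already logged.

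Of the 55335 entries in the count tables, 53437 matched a symbol of a GENCODE annotation of GRCm38, which supplied Ensembl IDs, coordinates, biotypes, exon numbers and transcript GC content. The 109 repeated symbols were kept apart as separate entries. Every column was used, and the tables of the 2 comparisons, which the authors normalized separately, were tested separately.

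The main test was edgeR 4.0.16 (quasi-likelihood, robust, TMM factors, filterByExpr defaults) in R 4.3.3 on the raw counts of the 6 libraries of each comparison, with no covariate and Benjamini-Hochberg adjusted p under 0.05. Levels are given as CPM after TMM scaling, as mean ± SD over 3 libraries, and fold changes as log2 values with SE. SE was taken as the unshrunken log2 fold change over the square root of the F statistic. Where all 3 libraries of a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. Where a group had 1 to 3 counts, the ratio is given with an exact 95% binomial interval, which covers counting error only.

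Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided) when at least 5 members were measured, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move 1 way without comparing them with other genes, stood beside it. The 28 lists covered cell types (M cell, mature enterocyte, stem cell, proliferation, Paneth, goblet, enteroendocrine, tuft, immune cell, stromal and endothelial cell, fetal-like and regenerative epithelium), position (proximal and distal intestine, lower-villus antimicrobial genes) and pathways. The pathways were RANK and NF-kB signalling, cholesterol biosynthesis, fatty acid oxidation with PPARA targets, retinol metabolism, interferon response, MHC class I and class II presentation, the integrated stress and unfolded protein responses, targets of NRF2, AhR and p53, hypoxia with glycolysis, Notch signalling and mitochondrially encoded mRNA. Counts of members are over all genes tested; adjusted over the list alone, they were the same except where stated.

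The design, the lists and the rule for naming genes were fixed before the data were examined. The rule named 24 genes in both comparisons whatever their result. It added the 8 largest rises and 8 largest falls per comparison among named genes past the threshold with an average log2 CPM of at least 1 and no overlap between groups. It also added 4 members per called list by smallest p, and 12 genes changed in opposite directions. Some genes that the rule named are not reported here. The overlap of the comparisons was tested with Fisher's exact test over genes, which are not independent of each other. No library is shared by the comparisons.

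The alternatives planned were DESeq2 1.42.0, RLE and upper-quartile factors, no filter and a stricter filter on low counts, limma on the deposited log2 tables, a replicate block, 1 fit over all 12 libraries, thinning to 1 depth, mitochondrial genes left out, and each library left out. After the data were seen, 4 more were added. They were offsets that remove a spline trend (5 df) of log2 CPM with GC content (fitted on genes with a mean count of at least 20), 2 ribosomal RNA loci left out, a minimum fold of 1.5, and RANKL II libraries 1 and 2 summed. Because the offsets are fitted on the same libraries, how small their p is carries no weight; whether a value passed the threshold with them is given only where it differs from the main test.

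The replicate numbers mark differentiation experiments, per the labels and the series design, so libraries with the same number were taken as paired by label, with no block in the main test. The values gave little sign of shared deviations, with correlations of 0.018, 0.14 and 0.031 in the RANKL comparison and 0.024, 0.037 and 0.058 in the CSRM617 comparison. The blocked value is printed where it changes a call. Tested on simulated data with the depth of the RANKL comparison, the test recovered 76% of genes changed 1.5-fold and 92% of those changed 2-fold, and called 0.0457% of unchanged genes, over 13341 genes. For the CSRM617 comparison the shares were 86%, 96% and 0.0655% over 13946 genes. These shares hold for simulated data without a GC trend and for changed genes with a mean count of at least 20. The same trend, rising with GC content, was then put into the treated libraries of both simulated comparisons. Without GC offsets the test called 31.44% of unchanged genes in the RANKL comparison and 51.11% in the CSRM617 comparison. With GC offsets it called 0.1679% and 0.06556%. Without offsets the simulated fold changes had Spearman correlations with GC of 0.849 and 0.892, against -0.31 and 0.565 in the data. The real RANKL trend thus had the other sign. A spline in GC content removes such a smooth trend almost by construction. The shares with offsets therefore do not show how well the offsets suit the real libraries. Sequence families whose members share reads (Defa, Gbp, Hspa1, Krt and Reg genes, and mitochondrial genes with nuclear copies) are uncertain at the level of the single gene.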

Results

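RNA was measured in 12 libraries of mouse small intestinal organoids, 3 each of the ENR control, RANKL, RANKL II and RANKL+CSRM617 groups. The labels and the series title place the study around ONECUT2, RANKL and the differentiation of enterocytes and M cells, the antigen-sampling cells of the epithelium over lymphoid tissue. Totals were 5795541 to 7577492 counts per library in ENR control, 6351155 to 7719157 in RANKL, 8669153 to 11241811 in RANKL II and 10225102 to 14041947 in RANKL+CSRM617. Gm26917 and Gm42418, loci that collect ribosomal RNA reads, took 29.47% ± 6.96 of the counts in ENR control, 10.09% ± 0.535 in RANKL, 6.596% ± 0.142 in RANKL II and 15.59% ± 0.275 in RANKL+CSRM617 (SD, n = 3). Mitochondrially encoded mRNA took 6.499% ± 1.3, 2.735% ± 0.198, 6.024% ± 0.0115 and 9.539% ± 1.3 in the same order. The nuclear RNAs Malat1 and Neat1, named after their values were seen, took 0.6748% to 0.757% and 0.04843% to 0.06348% in ENR control, 2.49% to 2.951% and 0.4353% to 0.4974% in RANKL, 3.326% to 3.449% and 0.715% to 0.725% in RANKL II, and 2.368% to 2.528% and 0.6643% to 0.674% in RANKL+CSRM617. Replicates are separate differentiation experiments per the series design, and all tests below compare 3 libraries with 3. They are thus not given as separate animals, and the p-values do not measure variation between animals.

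The first comparison asked what 6 days of RANKL changed against ENR medium. RANKL organoids had higher M cell genes and NF-kB genes, lower Lgr5 and Paneth cell genes, and enterocyte genes that moved in both directions. With an estimated correlation no gene list was called (adjusted p = 0.0641 for M cell and for NF-kB genes, adjusted p = 0.414 for Paneth genes), while with GC offsets as well M cell (0.0228) and NF-kB genes (0.0175) were. Spib, a transcription factor required for M cell maturation (chromosome 7, 44525993 to 44532071, minus strand, GRCm38), rose from 4.407 ± 1.84 to 257.2 ± 7.87 CPM. Lgr5, a receptor that marks crypt stem cells, fell from 424.6 ± 29.2 to 52.14 ± 1.21 CPM. Onecut2 (chromosome 18, 64340020 to 64400987, plus strand) rose from 196.9 ± 8.89 to 449.7 ± 17.8 CPM, a log2 change of 1.19 (SE 0.0783, edgeR adjusted p = 3.93e-09). With GC offsets its change was 0.84 (SE 0.0818).

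All 16 measured M cell genes rose with RANKL. The median log2 change was 5.15, or 4.55 with the 2 genes absent from ENR control set at their bounds (camera adjusted p = 2.88e-48, adjusted p = 0.0641 with an estimated correlation). Ccl20, a chemokine that draws CCR6-positive lymphocytes, rose by 6.33 (SE 0.212), Prnp, the prion protein, by 5.92, Anxa5 by 5.47, and Ccl9 by 4.83. Gp2, the receptor for FimH-bearing bacteria on mature M cells, had 0 counts in ENR control and 2.373 ± 0.375 CPM with RANKL, at least 13.6-fold higher. Sox8, a transcription factor upstream of Gp2, was at least 46.2-fold higher at 8.076 ± 0.562 CPM. Tnfaip2 rose by 1.60 (SE 0.223). The decoy receptor gene Tnfrsf11b was too low to be tested in either comparison.

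**Figure D1:**
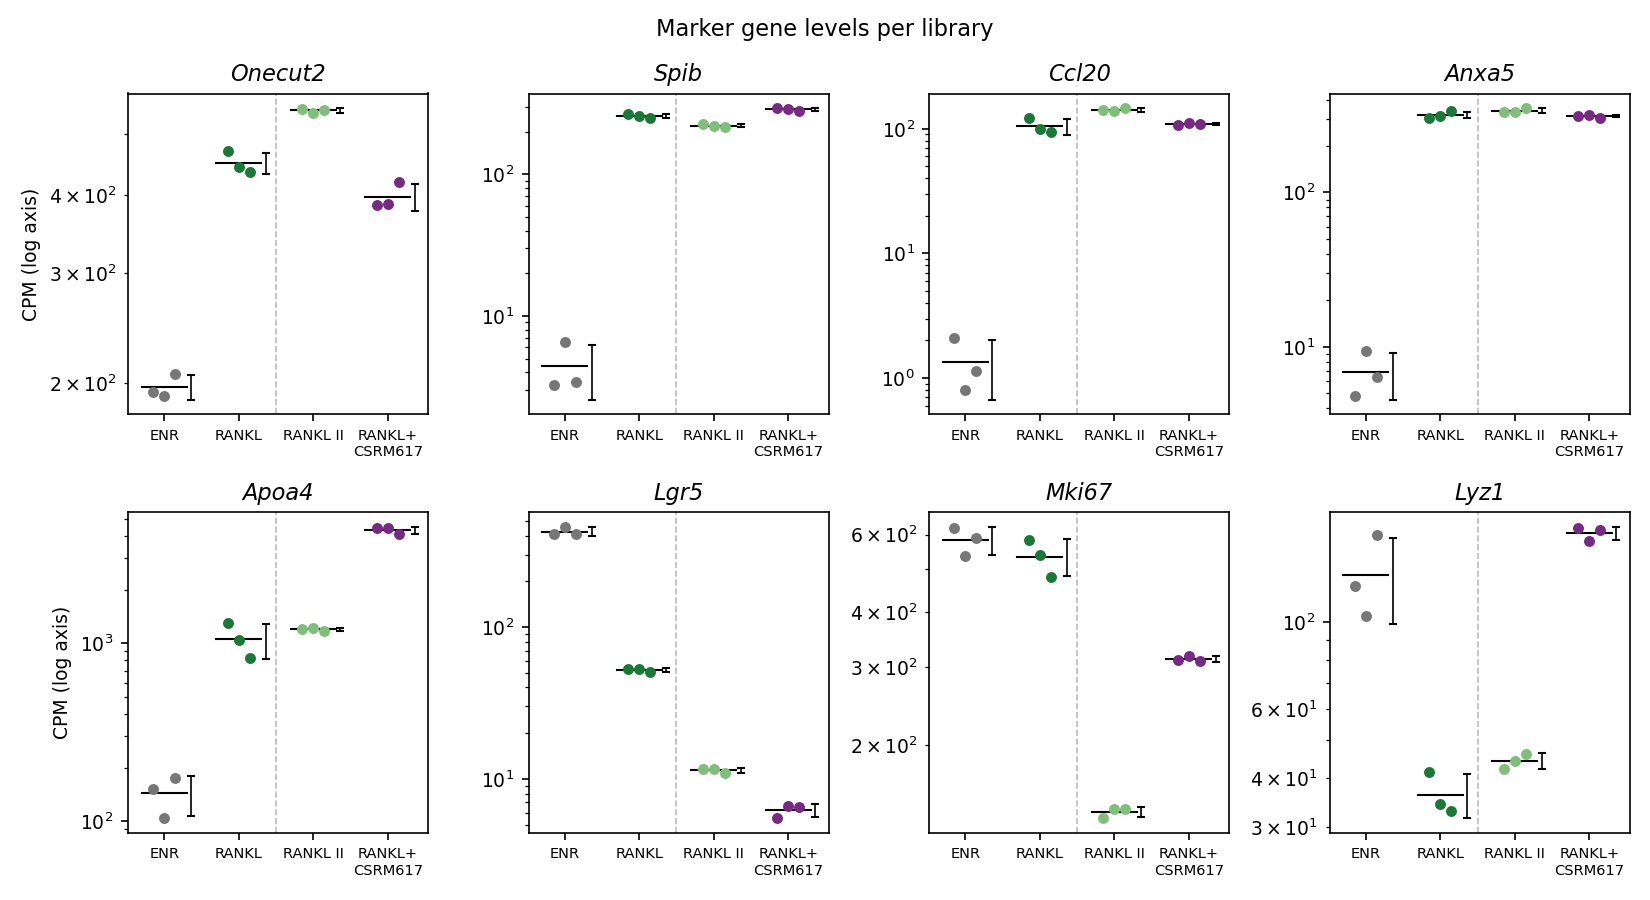
CPM after TMM scaling (log axis) of 8 genes in each of the 12 libraries; dots are libraries, horizontal lines group means, bars SD, and the dashed line parts the tables that were normalized separately. Spib stood at 257.2 CPM with RANKL against 4.407 in ENR control, and Apoa4 at 4327 CPM in RANKL+CSRM617 against 1197 in RANKL II.

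In the RANK and NF-kB list, 13 of 14 measured genes rose, with a median of 2.10 (camera adjusted p = 3.66e-23, adjusted p = 0.0641 with an estimated correlation). Tnfrsf11a, which encodes the RANKL receptor RANK (chromosome 1, 105780718 to 105847981, plus strand), rose by 2.12 (SE 0.0886) from 57.97 ± 3.29 to 251.7 ± 16 CPM. Nfkbie rose by 4.09, Tnfaip3 by 3.84 and Nfkbia by 3.45, 3 negative feedback genes of the pathway. Nfkb2 rose by 2.72 and Relb by 2.40, which encode the subunits of the noncanonical arm. The p53 targets gave 11 of 12 higher, with Trp53inp1 at 2.63, Cdkn1a, a cell cycle inhibitor, at 2.52 and Zmat3 at 2.43 (camera adjusted p = 1.92e-11, adjusted p = 0.14 with an estimated correlation).

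Stem cell genes were divided, with 7 higher and 8 lower of 18 (9 lower when adjusted over the list alone). Smoc2 fell by 2.51 (SE 0.0817) and Rgmb by 1.15, while Tnfrsf19 rose by 2.70 (SE 0.111). The list was called lower with a median of -0.35 (camera adjusted p = 0.0151, adjusted p = 0.335 with an estimated correlation). Olfm4 was at 664.9 ± 180 and 382.5 ± 116 CPM, a log2 change of -0.80 that did not pass (edgeR adjusted p = 0.0583) and passed with the replicate block at -0.82 (edgeR adjusted p = 0.0409; 0.00184 to 0.378 over its alternatives). It also passed without ENR control replicate 1 (-0.94), RANKL replicate 1 (-0.99) or RANKL replicate 3 (-0.57). Proliferation genes gave 14 lower of 20 and none higher, or 15 lower adjusted over the list alone, with Mcm5 at -1.31, Mcm6 at -1.13, Mcm3 at -1.09 and Mcm2 at -0.93, parts of the replicative helicase. That list had a median of -0.52 (camera adjusted p = 0.000702, adjusted p = 0.466 with an estimated correlation). Mki67 was at 582.7 ± 42.7 and 534.2 ± 51.9 CPM, a log2 change of -0.12 (edgeR adjusted p = 0.25) that passed without ENR control replicate 2 (-0.19) and with GC offsets (-0.26).

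Of 10 measured Paneth genes 9 fell and Mmp7, which encodes matrilysin, rose by 2.16 (SE 0.143). Habp2 fell by 2.92, Defa17 by 2.00 and Lyz1, the lysozyme of Paneth granules, by 1.84, from 131.3 ± 32.3 to 36.23 ± 4.64 CPM. The list median was -2.23 (camera adjusted p = 0.000321, adjusted p = 0.414 with an estimated correlation). Goblet genes gave 5 higher and 5 lower of 12, or 6 higher adjusted over the list alone. Zg16 rose by 4.25, Ccl6 by 4.16, Guca2a by 3.38 and Clca1 by 3.10, against Muc2, the main gel-forming mucin, at -0.87 (edgeR adjusted p = 0.00623, and 0.0511 with the replicate block; 3.5e-06 to 0.134 over its alternatives). The goblet list was called higher with a median of 0.25 (camera adjusted p = 0.0221, adjusted p = 0.466 with an estimated correlation), and the call was lost without ENR control replicate 2 (camera adjusted p = 0.192). Enteroendocrine genes gave 1 lower and none higher of 5 measured (camera adjusted p = 0.724), with Chga at -1.42 (SE 0.24). Tuft genes gave 8 higher of 11 with Dclk1 at 1.37, and the list missed the threshold (camera adjusted p = 0.0657). It passed with GC offsets (0.0387), or without ENR control replicate 1 (0.0444), ENR control replicate 3 (0.0432) or RANKL replicate 2 (0.048), within 0.0377 to 0.335 over its camera alternatives, with 0.00167 by fry.

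Mature enterocyte genes split into 10 higher and 13 lower of 28, and the list was not called (camera adjusted p = 0.89). Its median was -0.12, its mean 0.02, and camera and fry gave opposite signs. Apoa4, a lipoprotein component of absorptive cells, rose by 2.89 (SE 0.229), Alpi, the brush border alkaline phosphatase, by 1.98 and Apoa1 by 1.88. Fabp1, a fatty acid carrier, fell by 1.64 (SE 0.223), from 19.32 ± 4.98 to 6.008 ± 1.85 CPM. Sis, which encodes sucrase-isomaltase and has a GC content of 38.36%, rose by 0.85, a call that GC offsets ended at 0.26 (SE 0.143, edgeR adjusted p = 0.142; 1.38e-20 to 0.142 over its alternatives). In the distal intestine list 5 genes rose and 2 fell of 8, among them Cubn at 7.24 and Mep1a at 1.51, with Slc10a2, the ileal bile acid transporter, at least 12.5-fold higher. The list had a median of 1.50 (camera adjusted p = 0.0425, adjusted p = 0.464 with an estimated correlation) and was lost without ENR control replicate 2 (camera adjusted p = 0.185).

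Of the metabolic and stress lists, hypoxia with glycolysis gave 11 higher and 1 lower of 14, with Egln3 at 2.54, Pfkfb3 at 2.27, Slc2a1, a glucose transporter, at 1.24 and Ldha at 1.16 (median 1.05, camera adjusted p = 2.62e-07, adjusted p = 0.335 with an estimated correlation). Cholesterol biosynthesis gave 16 higher and 1 lower of 20, with Sc5d at 1.41, Mvd at 1.28 and Cyp51 at 1.26 (median 0.73, camera adjusted p = 0.000417, adjusted p = 0.466 with an estimated correlation). NRF2 targets gave 8 higher and 1 lower of 12, with Srxn1 at 2.25, Gclc at 1.77, Gsta4 at 0.71 and Gstm1 at -1.07 (median 0.61, camera adjusted p = 0.0151, adjusted p = 0.335 with an estimated correlation). Fetal-like and regenerative genes gave 6 higher of 7, with Ly6a at 3.54, Sprr1a at 3.06, Anxa1 at 1.10 and Krt7 at 0.91 (median 0.96, camera adjusted p = 0.00246, adjusted p = 0.414 with an estimated correlation). All 7 measured mitochondrially encoded mRNAs fell, with mt-Nd4 at -2.01, mt-Cytb at -1.97, mt-Nd5 at -1.84 and mt-Co1 at -1.72 (median -1.72 and -2.55 with GC offsets, camera adjusted p = 0.000803, adjusted p = 0.463 with an estimated correlation).

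The largest rises under the naming rule included genes with 0 counts in ENR control. Wnt10a was at least 194-fold higher, Dscam at least 149-fold, Camk2a at least 142-fold, Zbtb7c at least 131-fold, Ubd at least 104-fold, Sost at least 101-fold and Gbp9 at least 99.7-fold. Pglyrp2 had 3 counts in ENR control and 5221 with RANKL, a ratio of 1180 (interval 405 to 5740). The largest falls were Prss12, with 104 counts against 2 and a ratio of 76.5 (interval 20.7 to 640) in favour of ENR control, Prelp (-5.70), Gkn3 (-5.51), Cbs (-4.67), Pnliprp1 (-4.57), Slc7a8 (-4.56), Atp2c2 (-4.25) and Cps1 (-4.22), the mitochondrial carbamoyl phosphate synthetase.

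Other lists were not called. Lower-villus antimicrobial genes gave 6 higher and 2 lower of 9 (camera adjusted p = 0.0844, and 0.0214 with the replicate block). With GC offsets 3 were higher and 2 lower, and the median went from 0.47 to 0.21 (camera adjusted p = 0.108). The list passed without ENR control replicate 1 (0.0128), RANKL replicate 2 (0.048) or RANKL replicate 3 (0.05). Its adjusted p ran from 0.0128 to 0.392 over its camera alternatives, with 0.00171 by fry. Interferon response genes gave 4 higher and 2 lower of 13 (camera adjusted p = 0.672, and 0.0283 without ENR control replicate 1; 0.0283 to 0.89 over its camera alternatives, 0.374 by fry). MHC class I genes gave 5 higher of 8 (camera adjusted p = 0.118, and 0.0445 with GC offsets; 0.0419 to 0.56 over its camera alternatives, 0.0108 by fry). Proximal intestine genes gave 2 higher and 2 lower of 10 (0.71) and retinol metabolism 3 higher and 2 lower of 8 (0.74), as camera adjusted p. Fatty acid oxidation gave 3 higher (4 adjusted over the list alone) and 5 lower of 12 (0.268), the stress responses 2 higher and 4 lower of 14 (0.475), AhR targets 3 higher of 5 (0.22) and Notch genes 2 higher and 3 lower of 8 (0.354). Too few members were measured to test immune cell genes (1, not passed), stromal and endothelial genes (1 higher and 1 lower of 2) and MHC class II genes (2 higher of 3).

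Across 13570 genes tested, 3897 were higher and 3802 lower with RANKL by edgeR, of which 1500 and 904 changed at least 2-fold. With GC offsets the split was 3064 higher and 4539 lower. The fold changes fell with transcript GC content, from a median of 0.627 over 691 genes under 40% GC to -0.385 over 549 genes above 60% (Spearman -0.31 across 13383 genes). The ENR control libraries themselves differed, with slopes of log2 CPM (less the mean over all 12 libraries) per percent GC of 0.0203, -0.000712 and 0.0248 for replicates 1 to 3, against -0.00923, -0.0114 and -0.0128 with RANKL; the ribosomal RNA loci took 31.03%, 21.87% and 35.52% in the same controls. The control names begin with CVENR, which may stand for CHIR99021 and valproic acid in the controls too, but the labels do not spell this out; without it in the controls, these changes would include its effects.

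The second comparison asked what 40 µM CSRM617 changed on top of RANKL. RANKL+CSRM617 organoids had higher mature enterocyte and Paneth genes and lower stem cell genes than RANKL II, while M cell genes moved in both directions. Apoa4 rose from 1197 ± 25.9 to 4327 ± 203 CPM, Lyz1 from 44.17 ± 2.04 to 168.2 ± 6.7 CPM, and Gp2 fell from 2.075 ± 0.321 to 0.7119 ± 0.0589 CPM. Onecut2 itself was at 546.2 ± 4.83 in RANKL II and 397 ± 19.4 CPM with CSRM617, a log2 change of -0.46 (SE 0.0295, edgeR adjusted p = 4.82e-18), and at 0.04 (SE 0.0224) with GC offsets, which ended the call. The transcript has a GC content of 42.6%, and its level does not measure how far the protein was inhibited.

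The fold changes of this comparison rose with transcript GC content, from a median of -0.996 over 735 genes under 40% GC to 0.533 over 555 genes above 60% (Spearman 0.565 across 13964 genes, 0.0268 with GC offsets). Values with GC offsets are therefore given beside many of the results. Median GC ran from 46.19% to 56.91% over the lists, apart from mitochondrially encoded mRNA at 37.12%.

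**Figure D2:**
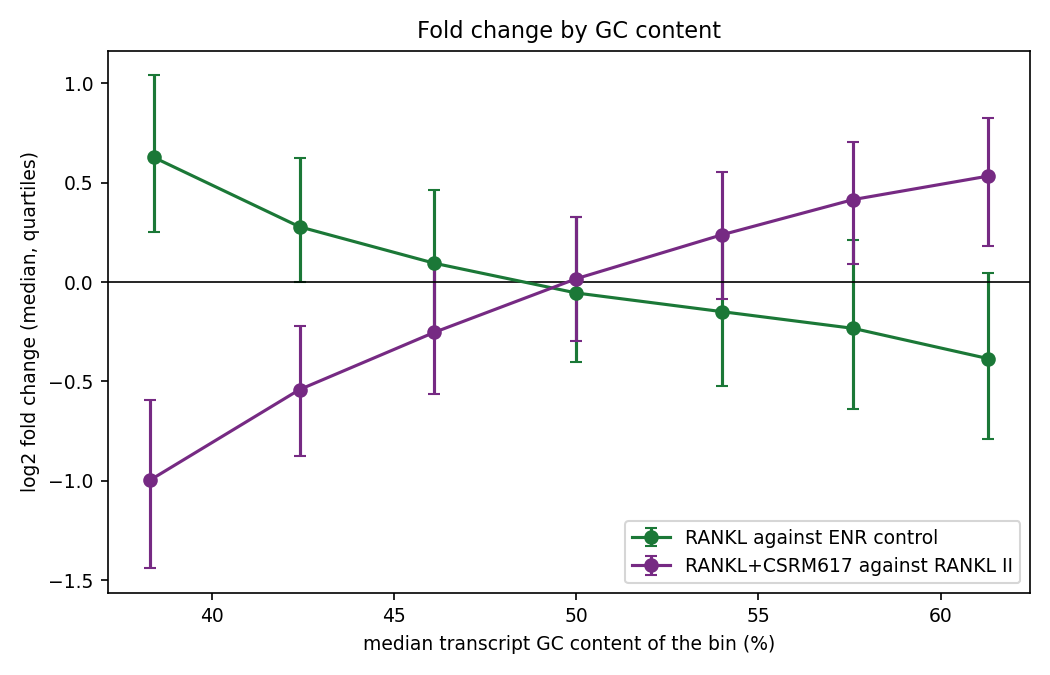
Median log2 fold change (points) with quartiles (bars) of genes in 7 bins of transcript GC content, against the median GC percent of each bin, for both comparisons. RANKL against ENR control fell from 0.627 to -0.385 and RANKL+CSRM617 against RANKL II rose from -0.996 to 0.533.

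Of 29 mature enterocyte genes 26 rose and 1 fell, with a median of 1.03 and 0.89 with GC offsets (camera adjusted p = 6.31e-24, adjusted p = 0.0239 with an estimated correlation). Fabp1 rose by 2.02 (SE 0.13), Creb3l3, a transcription factor of lipid metabolism, by 1.99, Mttp, which loads lipid on to apolipoprotein B, by 1.57, Apoa1 by 1.33 and Alpi by 1.12 (0.84 with offsets). Sis rose by 0.40 (SE 0.0758), and by 1.31 with GC offsets. Retinol metabolism gave 7 higher and 1 lower of 9, with Rbp2 at 2.65, Aldh1a1 at 1.87, Adh1 at 0.77 and Isx at 0.52 (median 0.63 and 0.39 with offsets, camera adjusted p = 0.000491, adjusted p = 0.172 with an estimated correlation). In the proximal intestine list 8 genes rose and 2 fell of 10, with Ckb at 1.87, Cyp2b10 at 0.97 and Adh6a at 0.83 (median 0.87, camera adjusted p = 0.0226, adjusted p = 0.218 with an estimated correlation). GC offsets ended that call (median 0.75, camera adjusted p = 0.0534; 0.0115 to 0.218 over its camera alternatives, 0.000129 by fry).

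Paneth genes gave 9 higher and 1 lower of 11, with a median of 1.92 and 2.04 with GC offsets (camera adjusted p = 9.33e-11, adjusted p = 0.0239 with an estimated correlation). Lyz1 rose by 1.92 (SE 0.0463), Itln1, an intelectin, by 1.74, Defa24, an alpha-defensin, by 1.57, and Mmp7 fell by 0.93. Lower-villus antimicrobial genes gave 6 higher and 2 lower of 9, with Nlrp6 at 1.49, Reg1 at 0.96 and Lypd8 at 0.47 (median 0.47, 0.42 with offsets). That list was called with a camera adjusted p = 0.034 (adjusted p = 0.209 with an estimated correlation) and lost without RANKL+CSRM617 replicate 3 (0.0738). Reg3g, a bactericidal lectin, fell by 0.34 (SE 0.0252), a call that GC offsets ended at -0.01 (SE 0.02). Goblet genes gave 5 higher and 5 lower of 12 (camera adjusted p = 0.878), with Muc2 at 0.98; the list median was -0.09 (-0.13 with offsets) and camera gave the direction as higher. Chga, a granin of enteroendocrine cells, rose by 1.58 and Dclk1 of tuft cells by 0.56, in lists with 4 higher of 7 and 8 higher and 2 lower of 11 that were not called (camera adjusted p = 0.184 for each; medians 0.83 and 0.64, or 0.44 and 0.37 with offsets).

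Stem cell genes gave 11 lower and 3 higher of 17, with a median of -0.40 and -0.54 with GC offsets (camera adjusted p = 4.8e-06, adjusted p = 0.0462 with an estimated correlation). Tnfrsf19 fell by 2.09, Cd44 by 1.19, Prom1 by 0.88, Cdk6 by 0.85 and Lgr5 by 0.85 (SE 0.125), the last from 11.38 ± 0.423 to 6.243 ± 0.632 CPM. Olfm4 rose by 0.82, from 19.58 ± 2.65 to 34.44 ± 0.986 CPM. Proliferation genes gave 10 higher and 2 lower of 20, with Plk1 at 1.29, Mki67 at 1.15, Cenpf at 0.84 and Top2a at 0.52 (0.95 with offsets; median 0.18 and 0.36 with offsets, camera adjusted p = 0.034, adjusted p = 0.193 with an estimated correlation). Mki67 rose from 140.9 ± 3.89 to 313.6 ± 4.41 CPM.

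M cell genes gave 8 higher and 7 lower of 16, and the list was not called (median 0.05 and -0.14 with offsets, camera adjusted p = 0.878). Gp2 fell by 1.56 (SE 0.315), Ccl9 by 0.94 (0.55 lower with GC offsets) and Anxa5 by 0.12 (0.23 lower with offsets; not called in the 1 fit over all 12 libraries, at -0.05, edgeR adjusted p = 0.5), while Tnfaip2 rose by 0.78 (SE 0.138; 0.49 with offsets). Spib rose by 0.38 (SE 0.0316) and Ccl20 fell by 0.38 (SE 0.0387), and each took the other sign with GC offsets, at -0.13 and 0.41. Sox8 rose by 0.24 (SE 0.0917, edgeR adjusted p = 0.0172) and stood at -0.23 with offsets. Its call was lost without RANKL II replicate 2 (0.21), RANKL II replicate 3 (0.20) or RANKL+CSRM617 replicate 2 (0.19). Tnfrsf11a was at 240.2 ± 3.59 and 246.3 ± 3.46 CPM, a log2 change of 0.04 (SE 0.0313) that did not pass (edgeR adjusted p = 0.308) and was called at 0.15 with GC offsets. RANK and NF-kB genes gave 10 higher and 4 lower of 15, with Map3k14, the kinase that opens the noncanonical arm, at 0.89, Nfkb2 at 0.83, Bcl3 at 0.75 and Relb at 0.52. With offsets Map3k14 stood at 0.57, Nfkb2 at 0.40 and Bcl3 at 0.36. The list had a median of 0.26 (camera adjusted p = 0.0154, adjusted p = 0.218 with an estimated correlation), and with GC offsets the list (median 0.07, camera adjusted p = 0.123; 0.00787 to 0.218 over its camera alternatives, 2.96e-05 by fry) and Relb (0.02, SE 0.0308) were no longer called.

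**Figure D3:**
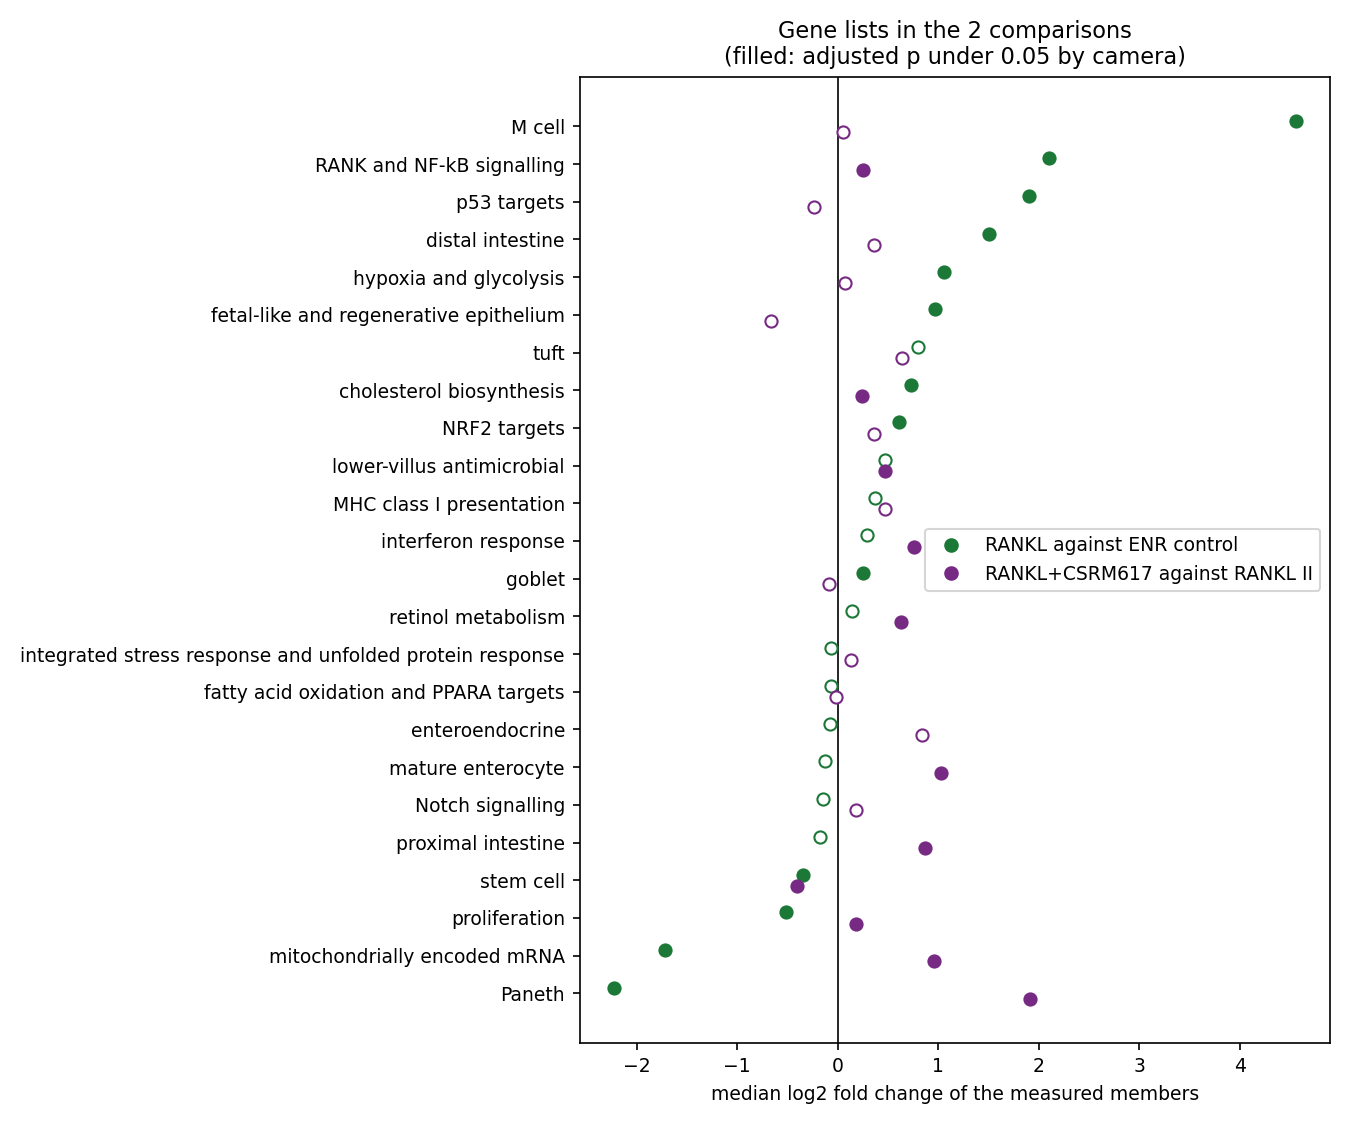
Median log2 fold change of the measured members of 24 gene lists in both comparisons, with genes absent from a group at their bounds; filled points have a camera adjusted p under 0.05. M cell genes stood at 4.55 with RANKL and 0.05 with CSRM617, and Paneth genes at -2.23 and 1.92.

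Interferon response genes gave 12 higher of 15 and none lower, with Oasl2 at 0.99, Irf7 at 0.93, Stat2 at 0.89 and Irf1 at 0.76 (Irf7 at 0.61 and Irf1 at 0.48 with offsets; list median 0.76 and 0.70 with offsets, camera adjusted p = 0.0273, adjusted p = 0.193 with an estimated correlation). In the 1 fit over all 12 libraries Oasl2 (1.05) and Irf7 (1.00) kept their size and were not called (edgeR adjusted p = 0.0984 and 0.0782). Cholesterol biosynthesis gave 12 higher and 5 lower of 20, with Mvk at 1.37 (median 0.24 and 0.27 with offsets, camera adjusted p = 0.034, adjusted p = 0.193 with an estimated correlation). All 7 measured mitochondrially encoded mRNAs rose, mt-Nd5 by 1.19, mt-Nd4 by 1.18, mt-Cytb by 1.09 and mt-Nd6 by 0.96 (median 0.96, camera adjusted p = 0.000641, adjusted p = 0.267 with an estimated correlation and 0.0323 with GC offsets as well). Their GC content is at the low end of the genes, and GC offsets raised the median to 2.12, with mt-Nd5 at 2.23, mt-Nd4 at 2.39, mt-Cytb at 1.92 and mt-Nd6 at 2.36.

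The largest rises were Enpp7 (4.85, SE 0.3), an alkaline sphingomyelinase of the brush border, Krt12 (3.34), Iqcn (3.26), Hspa1b (3.06), Defa29 (3.04), Nav3 (2.94), Egr2 (2.92) and Mptx2 (2.82). The largest falls were Khdc1a (-3.66, SE 0.276), Krt17 (-3.32), Abca4 (-3.19), Enpp2 (-3.09), Timp3 (-2.96), Krt16 (-2.95), Zfp97 (-2.95, or -1.98 with GC offsets) and Aif1l (-2.93). Among lists not called, fetal-like genes gave 2 higher and 5 lower of 8 (camera adjusted p = 0.158, and 0.0235 with GC offsets; 0.0235 to 0.284 over its camera alternatives, 0.000614 by fry), p53 targets 5 higher and 7 lower of 12 (0.146), and hypoxia with glycolysis 7 higher and 3 lower of 14 (0.353), or 3 higher and 9 lower with GC offsets. Distal intestine genes gave 6 higher and 3 lower of 10 (camera adjusted p = 0.107) and MHC class I 6 higher and 1 lower of 8 (0.129). The stress responses gave 7 higher and 4 lower of 14 (camera adjusted p = 0.158), or 5 higher and 6 lower with GC offsets. NRF2 targets gave 7 higher and 2 lower of 12 (camera adjusted p = 0.319) and fatty acid oxidation 5 higher and 5 lower of 13 (0.184). Notch genes gave 4 higher of 8 and none lower (camera adjusted p = 0.158), or 3 higher and 3 lower with GC offsets. Lists with under 5 measured members gave 1 higher of 2 immune cell genes (1 higher and 1 lower adjusted over the list alone), 1 higher of 1 stromal gene, 2 higher and 1 lower of 4 MHC class II genes and 2 higher and 1 lower of 4 AhR targets.

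Across 14167 genes, 4980 were higher and 5134 lower with CSRM617 by edgeR, of which 697 and 1159 changed at least 2-fold, or 521 and 598 with GC offsets. The biological coefficient of variation was 0.0287, against 0.0829 in the RANKL comparison, so changes far under 2-fold passed. The 3 RANKL II libraries differed by little more than counting noise, with median dispersion indices of 1.079, 1.123 and 1.131 per pair where counting noise alone gives 1, against 1.413 to 4.173 among ENR control, 1.477 to 2.234 among RANKL and 1.128 to 1.718 among RANKL+CSRM617 libraries, where replicates 1 and 2 gave the 1.128. The chi-square over its degrees of freedom ran from 1.104 to 1.43 over the RANKL II pairs. The RANKL II libraries were kept as 3 because the labels give them as 3 experiments, and the p-values would measure technical spread if they were not separate cultures.

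The third comparison asked whether CSRM617 moved the genes that RANKL moved. Of 13260 genes tested in both, 2076 were higher with RANKL and lower with CSRM617, where independent calls would give 1431, and 1900 were lower with RANKL and higher with CSRM617, against 1307. Genes called with equal signs numbered 1021 higher in both and 745 lower in both, against 1374 and 1362. The odds ratios were 2.69 and 2.58 (Fisher's exact test across genes, p = 7.638e-141 and 1.364e-124, two-sided), or 1.77 and 1.70 with GC offsets, and the Spearman correlation of the fold changes across genes was -0.305. Among genes changed at least 2-fold in both, 275 and 149 had opposite signs against 92 higher in both and 26 lower in both, an odds ratio of 17.0, or 9.1 with GC offsets.

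Genes raised by RANKL and lowered by CSRM617 with the smallest adjusted p included Prnp (5.92 and -0.57), Itgav, an integrin subunit (3.84 and -0.49), Ccl9 (4.83 and -0.94), Tfcp2l1 (3.18 and -0.46), Zmat3 (2.43 and -0.52), Reg3g (4.34 and -0.34), Asah2 (2.94 and -0.33) and Prkaa2 (2.58 and -0.72). The falls of Reg3g, Asah2 and Prkaa2 with CSRM617 were not called with GC offsets, at -0.01, -0.05 and -0.05. The other way round were Vipr1 (-2.11 and 0.81), Pigr, which carries IgA across the epithelium (-2.07 and 0.63), and Aldh1b1 (-2.41 and 0.58). With GC offsets the rises of Vipr1, Pigr and Aldh1b1 with CSRM617 stood at 0.35, 0.54 and 0.24. As sets, the 3847 genes raised by RANKL had a median of -0.26 with CSRM617 (camera p = 8.7e-07, p = 0.0191 with an estimated correlation), and the 3660 lowered genes a median of 0.23 (camera p = 8.71e-08, p = 0.0178 with an estimated correlation). With GC offsets the 3847 raised genes had a median of -0.0726 and the 3660 lowered genes a median of 0.0793. With GC offsets in both fits the opposed counts were 1283 and 1822 (978 and 1469 for independent calls), and the correlation was -0.14.

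RANKL and RANKL II, both labelled as 6 days of RANKL, were normalized in separate tables and were not tested against each other. Side by side, Lgr5 was at 52.14 ± 1.21 and 11.38 ± 0.423 CPM, Olfm4 at 382.5 ± 116 and 19.58 ± 2.65, Mki67 at 534.2 ± 51.9 and 140.9 ± 3.89, and Sox8 at 8.076 ± 0.562 and 17.07 ± 1.55. These were among the genes that differed most of the 24 named in both comparisons. Tnfaip2 (11.08 and 5.903) and Dclk1 (30.15 and 15.74) also differed. Closer were Spib at 257.2 and 221 CPM, Tnfrsf11a at 251.7 and 240.2, Anxa5 at 317.3 and 338.9, and Alpi at 240.7 and 230.2.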

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

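Of the counts and correlations compared over the alternatives, 246 stayed within a tolerance of the main value and 25 moved beyond it. For the Spearman correlation the tolerance was 0.05. For counts it was wide, so values within it were not always close to the main value. With GC offsets, 3064 genes higher with RANKL were within it, against 3897 in the main test. So were 521 genes at least 2-fold higher with CSRM617, against 697. For single genes 3614 values had the same status as in the main test, called or not called. A call was gained by 11 and lost by 41, and 9 changed sign. For single lists the numbers were 590, 32, 28 and 11. The 3614 and the 590 include results called in neither, so they do not count calls that were kept.

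In the RANKL comparison a minimum fold of 1.5 left 1601 genes higher and 1162 lower, which follows from the stricter null. By limma on the deposited log2 values, 690 genes were at least 2-fold higher and 417 at least 2-fold lower; the cause was not tested. DESeq2 gave 3388 higher and 3228 lower, and leaving out each library gave 3362 to 4132 higher and 3287 to 4068 lower. With an estimated correlation 0 lists were called higher and 0 lower. The mature enterocyte list changed sign with GC offsets (camera adjusted p = 0.963), with fry (adjusted p = 0.882) and without RANKL replicate 3, at 0.692 to 0.962 over the libraries left out. The replicate block changed no call in either comparison beyond those of Olfm4, Muc2 and the lower-villus list with RANKL. The retinol metabolism list changed sign without RANKL replicate 1, at 0.738 to 0.873 over the libraries left out.

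In the CSRM617 comparison a minimum fold of 1.5 left 1359 genes higher and 1675 lower. By limma on the deposited log2 values, 187 genes were at least 2-fold higher and 218 at least 2-fold lower. GC offsets left 598 genes at least 2-fold lower, and 596 with the replicate block as well. DESeq2 gave 4329 higher and 4118 lower, and leaving out each library gave 4714 to 5037 higher and 4781 to 5084 lower. With an estimated correlation 2 lists were called higher. Fry called 18 lists higher and 4 lower, a test that does not compare a list with other genes. GC offsets gave 2 lists lower, and 2 with the replicate block.

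Genes of the CSRM617 comparison that changed sign did so with GC offsets, without and with the replicate block: Onecut2 at 0.036 and 0.037, Spib at -0.125 and -0.124, Ccl20 at 0.406 and 0.405, and Sox8 at -0.230 and -0.231. Tnfrsf11a stood at -0.0065 with upper-quartile factors. DESeq2 did not call Sox8 (adjusted p = 0.111).

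The M cell list of the CSRM617 comparison changed sign with GC offsets (camera adjusted p = 0.564, and 0.570 with the block), as did the goblet list (0.507 and 0.516) and the hypoxia and glycolysis list (0.394 and 0.356). The goblet list also changed sign without RANKL II replicate 3, at 0.733 to 0.990 over the libraries left out.

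For genes changed in opposite directions, those raised by RANKL and lowered by CSRM617 numbered 1283 with GC offsets, 1322 with the block as well, and 275 at at least 2-fold in both, where 149 were lowered by RANKL and raised by CSRM617. The Spearman correlation was -0.179 with DESeq2, which kept more genes of low count, -0.140 with GC offsets and -0.143 with the block as well. It ran from -0.372 without ENR control replicate 2 to -0.258 without ENR control replicate 3.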

Other observations

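The immediate-early genes, the symbol families and the noise test of the RANKL II libraries were chosen after values had been seen; the GC offsets, the ribosomal loci left out, the minimum fold of 1.5 and the summed RANKL II libraries were added after the data were seen. Of 14 immediate-early genes, which respond to stress and growth signals within minutes, 11 rose with CSRM617 and 3 fell; they were not tested as a set. Fos rose from 35.98 ± 1.4 to 161.2 ± 8.98 CPM, a log2 change of 2.16 (SE 0.0497), Jun by 2.48 (SE 0.0432), Fosb by 2.79, Atf3 by 2.45 and Egr1 by 1.52. With GC offsets these stood at 1.85, 2.18, 2.48, 2.37 and 1.23. Others that rose shrank more with GC offsets: Ier2 from 1.10 to 0.61, Klf4 from 0.83 to 0.27, Junb from 0.72 to 0.16 and Nr4a1 from 0.68 to 0.37. Egr2 went from 2.92 to 2.74 and Dusp1 from 1.42 to 1.23. Ier3 fell by 0.77, Myc by 0.42 and Klf6 by 0.34, or by 1.02, 0.72 and 0.26 with GC offsets. With RANKL alone, 5 of 12 measured rose and 5 fell: Ier3 rose by 1.61, Klf6 by 1.60, Junb by 0.98, Dusp1 by 0.75 and Fos by 0.71, while Jun fell by 1.19, Ier2 by 1.14, Egr1 by 1.00, Nr4a1 by 0.68 and Myc by 0.53.

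Families of genes that share a symbol stem gave further groups. With RANKL, 51 of 55 Hist genes fell and none rose (median -0.88, camera adjusted p = 4.2e-11, adjusted p = 0.995 with an estimated correlation), as did 49 of 63 Rpl genes (median -0.67, camera adjusted p = 2e-08, adjusted p = 0.995 with an estimated correlation). With CSRM617, 16 of 19 Myo genes rose and 2 fell (median 0.76 and 0.61 with GC offsets, camera adjusted p = 9.76e-09, adjusted p = 0.436 with an estimated correlation), with Myo15b at 1.21, Myo1a, a brush border myosin, at 1.18 and Myo7b at 0.59. No family was called with an estimated correlation in either comparison.

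The GC slope of the CSRM617 fold changes was above 0 by more than 2 SE in each of the 7 annotated RNA classes with at least 100 tested genes, and smallest in units of its SE in processed transcripts (0.0666 log2 per percent GC, SE 0.0095). In sign this is consistent with a GC bias of the libraries that acts on every class, but the slopes were not equal: 0.0563 (SE 0.00089) in protein-coding genes, 0.0959 (SE 0.0079) in sense intronic and 0.0913 (SE 0.0039) in TEC transcripts. After thinning to 1 depth the Spearman correlation was 0.567. Thinning lowers counts but keeps the expected share of each gene, so this value could hardly have changed and does not decide on depth. Less unspliced or nuclear RNA, which the steeper classes could reflect, stays open: protein-coding genes with 1 exon had a slope of 0.0318 (SE 0.006, 242 genes) against 0.0571 (SE 9e-04) with several exons, between the bounds set in advance, and nuclear Malat1 took 3.326% to 3.449% of counts in RANKL II and 2.368% to 2.528% with CSRM617, while Neat1 moved less (0.715% to 0.725% and 0.6643% to 0.674%). Both are shares of all counts, so the rise of the ribosomal RNA loci from 6.596% in RANKL II to 15.59% with CSRM617 lowers them by itself. That lowering is smaller than the fall of Malat1 and larger than the fall of Neat1, so these nuclear RNAs did not move alike. A transcriptional effect of CSRM617 on GC-poor genes could not be parted from a bias, since every treated library differs from every untreated one.

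The opposed fold changes of RANKL and CSRM617 had a Spearman correlation of -0.14 with GC offsets in both fits, against -0.305 without, which leaves a shared GC trend open as the source of part of it. The value lies between bounds of -0.05 and -0.15 that were set before it was known, rewritten after it was seen, and then restored. Among genes changed at least 2-fold in both, the odds ratio of opposite signs was 9.1 with GC offsets. An effect of CSRM617 against part of the RANKL response would give this, but so could a shared difference in RNA composition. Ribosomal RNA loci went from 29.47% to 10.09% with RANKL and from 6.596% to 15.59% with CSRM617. Mitochondrially encoded mRNA went from 6.499% to 2.735% and from 6.024% to 9.539%. The odds ratio cannot part these sources. One hypothesis is that ONECUT2 holds back enterocyte and Paneth genes during RANKL treatment, so that its inhibition may release Apoa4 and Lyz1 while Gp2 falls. Gp2 was low in both groups (2.075 and 0.7119 CPM) and does not stand for the M cell list. That list gave 8 higher and 7 lower of 16 with CSRM617 and was not called. In the RANKL comparison, where Onecut2 rose by 1.19 (0.84 with GC offsets), Lyz1 fell by 1.84 (1.97 with offsets). Apoa4 rose by 2.89 there, which the hypothesis does not predict. Genetic loss of ONECUT2 with RANKL would test the hypothesis, since a small molecule may act elsewhere.

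The RANKL II libraries had a highest median dispersion index of 1.131 over their 3 pairs, which is consistent with repeat libraries of 1 culture or RNA and was tested after the values were seen. RANKL+CSRM617 replicates 1 and 2 were as close (1.128), and separate cultures with little variation could give such values. With RANKL II libraries 1 and 2 summed, 5074 genes were higher and 5196 lower, against 4980 and 5134, so the counts did not fall, though library 3 still stood as separate. If all 3 are repeats, the error in the CSRM617 comparison may be too small.

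Regrouping the 6 libraries of a comparison gives 10 splits. The true split alone reached its number of genes in each comparison (1 of 10 and 1 of 10; 7699 and 10114 genes, against 0 and 0 at most in the others). It was also alone for lists (1 of 10 and 1 of 10), with 13 lists against 6 to 12 in the RANKL comparison. In the CSRM617 comparison it gave 11 lists against 1 to 5. Every other split thus called lists by camera with the preset correlation while no gene was called. Those splits still hold part of the true difference, since each puts more libraries of 1 true group on 1 side. With 10 splits no share under 0.05 can be reached.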
